A study of Mus musculus with 8 samples.

How the data were processed

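Single-cell libraries were made with Chromium Single Cell 3' v3.1 chemistry, which tags each transcript with a unique molecular identifier (UMI), from cells pooled over 5 to 10 mice per library, per the labels' protocols. The stroma gate excluded CD45, lineage, Ter119 and CD71 positive cells, healthy haematopoietic cells were gated as Lin- and leukaemia cells as GFP+ Lin-, per the labels. Each of the 8 groups had 1 library. The deposited matrices hold raw UMI counts per gene and barcode, with no normalization. Cell Ranger 5.0.0, Seurat 4.3.0 and the genome build mm10 are named per the submitters' processing notes, and the annotation release is not given in the sources used here. Matrices of 2 libraries were analysed, leukaemia cells in WT recipients and the library labelled KO normal stroma. For the other 6 libraries barcodes were counted and matrices were not used here, so no expression was compared between WT and KO. All 8 feature lists were identical, with 32285 genes.

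Cells were kept with at least 500 detected genes and at most 10% mitochondrial UMIs. Doublets were scored with Scrublet as implemented in scanpy 1.11.5, with an expected rate of 0.8% per 1000 barcodes. In the leukaemia library the automatic threshold marked 1 cell (0.009%), so the 8.87% of barcodes with the highest scores (984) were removed. In the stroma library the automatic threshold removed 199 barcodes (2.15%), against an expected 7.42%. The 2 libraries were thus filtered by different rules, and doublets may remain among the stroma cells. Filtering kept 78.45% of leukaemia and 85.34% of stroma barcodes, with medians of 10901.5 and 13604 UMIs per kept cell. Each library was clustered alone on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9), with counts scaled to 10000 per cell. Genes of the 12 reported lists, mitochondrial genes and Xist were left out of the clustering. Other genes that vary with the listed ones could stay in, such as Ube2c and Cenpf, among the leading genes of leukaemia cluster 6. List counts by cluster are therefore not independent of the clustering.

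Clusters were named "-like" from markers of 23 classes fixed before the data were examined. The scoring rule was set after the clusters had been seen. A name needed a mean marker log2 ratio of at least 1 (with 20 CPM added), at least 3 markers raised 2-fold at 20 CPM or more, no class with more markers than the named one among the 10 leading genes, and a marker among the 30 leading genes. A cluster whose median UMIs times 3 fell short of its library's median needed a marker among the 10 leading genes. A neutrophil name was withdrawn where non-classical monocyte genes led the cluster, which left leukaemia cluster 17 (0.506%) unnamed.

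Levels were computed as UMIs summed over cells per 1000000 UMIs, with exact Poisson intervals. Ratios had exact conditional intervals and shares exact Clopper-Pearson intervals, all at 95%, and all cover counting error only. A class was compared with the other kept cells of its library. A list member counted as measured with at least 50 UMIs, and as 2-fold higher or lower on the log2 scale with 1 CPM added. A fold against 0 UMIs was given as the ratio to an assumed 3 counts, which is not the lower limit of its interval. List medians were ranked among 10000 random lists of equal size matched on expression. The stroma-to-leukaemia percentile was 99.95 for LIFR and IL6-family genes, 100.0 for niche factors, 0.37 for their receptors, 0.0 for the MLL-AF9 programme, 3.11 for MHC class I and 0.01 for MHC class II. It was 99.07 for interferon response, 2.64 for immune checkpoints, 99.96 for inflammatory cytokines, 0.0 for proliferation, 100.0 for extracellular matrix and 99.94 for immediate-early genes. These describe the libraries and are not tests.

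The lists and the rule for named genes were fixed before the data were examined. The rule took Lxn, Lif, Lifr, Il6st, Osm and Osmr. Within each library it took up to 4 members per list with the largest ratio in their highest class of at least 50 cells. Between libraries it took up to 2 list members per direction at 50 CPM or more, and 5 genes per direction outside the lists at 200 CPM or more. Genes named outside it (Gfm1, Hoxa9, Meis1) and the levels in classes other than those the rule picked (Mecom in leukaemia cluster 11, Cxcl12 and Kitl in LepR+ mesenchymal stromal-like cells) were chosen after their values were seen. Of 253 list genes 252 were found by symbol (Mx1 was not), and of 237 markers 236 (Wisp2 was not). Gene positions came from GENCODE vM21 on mm10, which may not be the annotation the authors used.

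Alternatives covered the filters on genes, mitochondrial share and doublets, the clustering settings, averaging of per-cell CPM, thinning to 2000 UMIs, the pseudocount, the library total, and all deposited barcodes. Where an alternative reclustered the cells, a numbered cluster was replaced by the new cluster with the largest overlap, as shared cells over all cells of both. No minimum overlap was set, so such values can be for different cells. Leaving out leukaemia cluster 1, or the haematopoietic classes of the stroma library, was chosen after seeing the data. The level and interval computation was tested on simulated counts with 200 changed genes per library. With monocyte-like cells simulated over 14049 genes, a true 2-fold change was recovered as 2.003 at the median over 52 genes. At the total of fibroblast-like cells, over 17238 genes, a true 2-fold change was recovered as 1.994, and 96.2% of the intervals held it. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19 and matplotlib 3.10.9 were used.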

Results

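Single-cell RNA sequencing was made from mouse bone marrow for 8 libraries, each the only library of its group and each pooled over 5 to 10 mice per the labels. The groups crossed wild-type (WT) with latexin-knockout (KO) mice, healthy marrow with MLL-AF9 leukaemia, and sorted stroma with haematopoietic cells. Latexin (Lxn), a carboxypeptidase inhibitor that restrains haematopoietic stem cell numbers, was the deleted gene. In the leukaemia groups the haematopoietic cells were GFP+ Lin- leukaemia cells from WT or KO recipients. WT or KO is there the recipient's genotype, and the sample titles do not give the leukaemia cells' own. Expression is described for the leukaemia cells in WT recipients and for the library labelled KO normal stroma, and the matrices of the other 6 libraries were not analysed here. The leukaemia library held 131057766 UMIs over 11088 barcodes, with a median of 10032 UMIs and 3233 genes per barcode. The stroma library held 140676178 UMIs over 9275 barcodes, with a median of 12627 UMIs and 3847 genes. After filtering, 8698 leukaemia cells and 7915 stroma cells were kept. Levels are counts per 1000000 UMIs (CPM) summed over kept cells, and values in parentheses after a level, fold or share are 95% intervals that cover counting error only. No group had a replicate, so groups were not tested against each other.

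The barcode counts address how many cells the libraries labelled WT and KO yielded. The library labelled KO normal stroma held 9275 barcodes and the one labelled WT normal stroma 12378, a ratio of 0.749 (0.729 to 0.770). Among normal Lin- haematopoietic cells the library labelled KO held 11297 barcodes and the one labelled WT 10320, a ratio of 1.095 (1.066 to 1.124). Leukaemia cells gave 12012 barcodes from KO recipients and 11088 from WT recipients, a ratio of 1.083 (1.056 to 1.112). Leukaemia stroma gave 12472 barcodes in the library labelled KO and 12268 in the one labelled WT, and the interval of their ratio, 1.017 (0.992 to 1.042), held 1. The number of cells loaded sets these counts, so they measure no frequency in the marrow.

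The level of Lxn addresses whether the deleted gene follows the labels. Lxn (ENSMUSG00000047557) was detected in the library labelled KO normal stroma, with 9298 UMIs or 71.2 CPM (69.8 to 72.7). It was 2.78-fold (2.67 to 2.90) higher there than in the leukaemia cells of WT recipients, which held 2827 UMIs or 25.6 CPM (24.7 to 26.6). WT is here the genotype of the recipient, and the sample titles do not give that of the leukaemia cells. These cells are therefore no WT reference for Lxn. Within the stroma library Lxn was highest in chondrocyte-like cells at 198 CPM (191 to 205) and lowest in skeletal muscle-like cells at 4.19 CPM (2.34 to 6.90). Fibroblast-like cells had 36.6 CPM, LepR+ mesenchymal stromal-like cells 54.4 CPM and osteolineage-like cells 75.6 CPM. In the leukaemia library Lxn ran from 4.52 CPM (2.26 to 8.09) in plasma cell-like cells to 34.9 CPM (30.9 to 39.4) in cluster 4. The Lxn gene lies at 67457998 to 67463926 on chromosome 3 of mm10, on the minus strand, within the span of Gfm1 on the plus strand. Gfm1, which encodes a mitochondrial elongation factor, had 13.9 CPM in stroma and 14.5 CPM in leukaemia cells. The labels do not give the deleted part of the gene, so 3' tags outside it check nothing, and no WT stroma matrix was analysed here.

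The class shares of the leukaemia library address which cell states the GFP+ Lin- sort held. Monocyte-like cells made up 4.79% of kept cells (4.35 to 5.26), granulocyte-monocyte progenitor-like cells 4.3% (3.88 to 4.75) and plasma cell-like cells 1.33% (1.10 to 1.60). Mast or basophil-like cells made up 0.644% (0.487 to 0.835), eosinophil-like cells 0.368% (0.252 to 0.519) and neutrophil-like cells 0.333% (0.223 to 0.479). Most cells fell in clusters that the marker rule left unnamed. The rule scores a cluster against the other cells of its library, so a trait that most cells share scores low. Some unnamed clusters had genes of mature cells among their leading genes, such as Lyz2 and Chil3 in cluster 7 and Hbb-bs and Pf4 in cluster 14. Cluster 0, led by Pde3b, Satb1, Npy and Cd34, held 13.4%, cluster 6, led by the mitotic genes Top2a, Birc5 and Mki67, held 7.92%, and cluster 10, led by the DNA replication genes Lig1, Pola1 and Mcm6, held 3.69%. Cluster 5, led by H2-Aa, Cd74 and Ifitm3, held 8.06% and missed the monocyte name by a marker score of 0.953 against a minimum of 1. The monocyte-like share was 11.6% with at most 5% mitochondrial UMIs, 12.2% without doublet removal and 13.3% at clustering resolution 0.5. No cluster took the granulocyte-monocyte progenitor name with at most 20% mitochondrial UMIs, without doublet removal, at resolution 0.5 or with 30 neighbours, so that class was lost there.

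**Figure D1:**
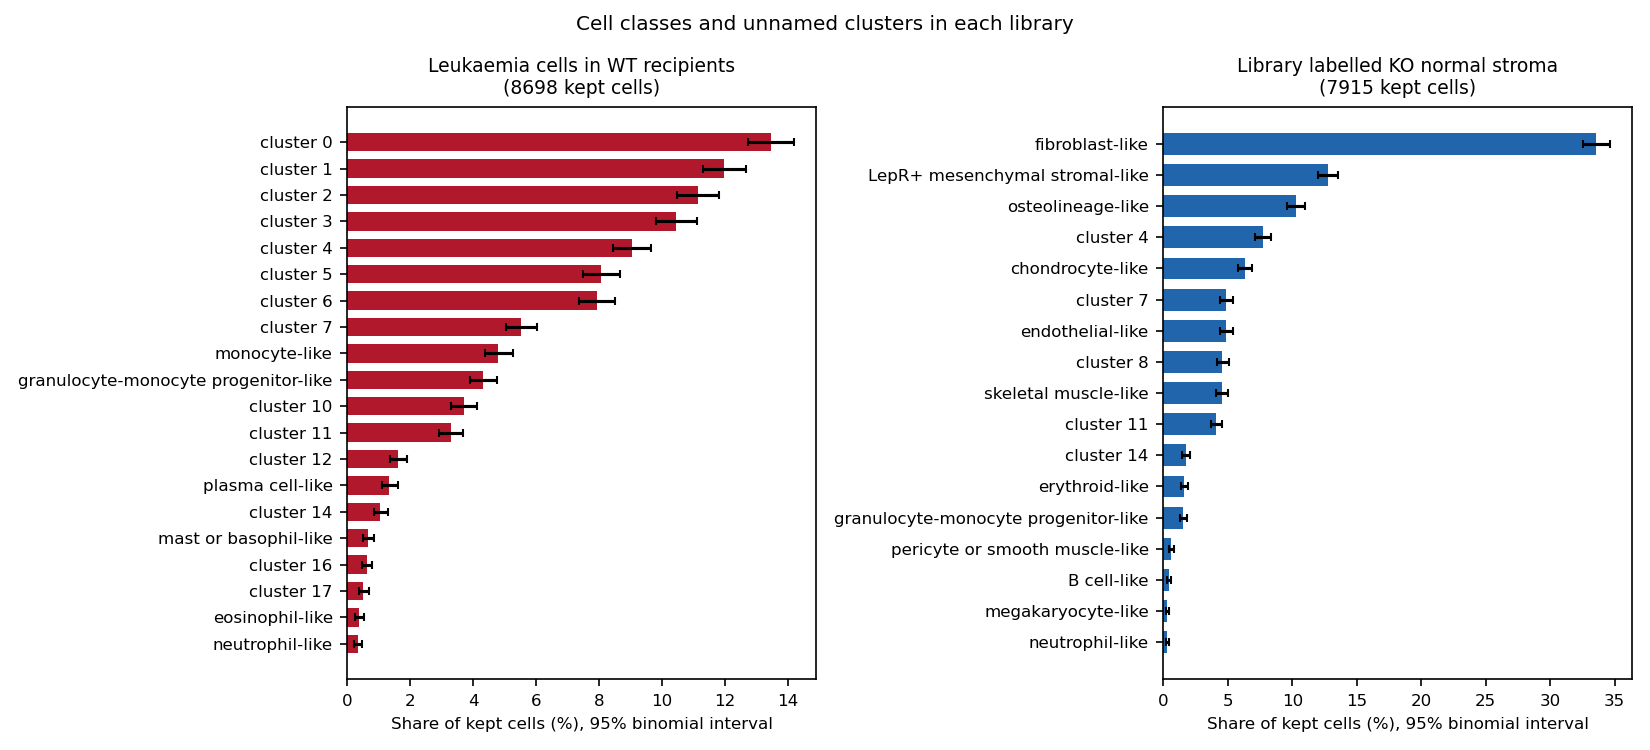
Share of kept cells (%) in each named class or unnamed cluster of the leukaemia library (left, 8698 cells) and of the library labelled KO normal stroma (right, 7915 cells). Bars start at 0 and whiskers are 95% exact binomial intervals, which cover counting error only.

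The gene lists in the leukaemia library address which leukaemia cells carried LIFR signalling, antigen presentation and immune genes. Cluster 5 had the broadest immune profile, with 18 of 20 interferon response genes and 8 of 10 MHC class II genes at least 2-fold above the other cells. There Ifit3, an interferon-induced antiviral gene, was 52.4-fold (37.7 to 74.03) higher, and Irf7, which drives type I interferon production, 12.8-fold (11.7 to 14.1) higher. H2-Aa, an MHC class II chain, reached 382 CPM against 8.09 CPM, and Ciita, the master regulator of MHC class II, was 24.3-fold (19.1 to 31.1) higher. Monocyte-like cells had 12 of 20 interferon genes at least 2-fold higher, a count that fell to 5 when per-cell CPM were averaged, when cells were thinned and with a pseudocount of 10 CPM. They also had 229 CPM of Tgfbi, a secreted matrix protein of monocytes, against 17.3 CPM, and Lilrb4a, an inhibitory myeloid receptor, was 20.3-fold (17.8 to 23.2) higher. MHC class I genes differed little in these cells, with 2 of 13 at least 2-fold higher in cluster 5 and 0 of 13 in monocyte-like cells. Elsewhere H2-Q7 was 5.46-fold (3.83 to 7.55) higher in mast or basophil-like cells, and cluster 1 had 1 of 13 at least 2-fold higher and 3 lower.

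Lifr (ENSMUSG00000054263), the receptor chain for leukaemia inhibitory factor, was sparse in the leukaemia library at 9.81 CPM (9.23 to 10.4). Its highest levels were 56.9 CPM (49.3 to 65.3) in cluster 1, 54.00 CPM (48.02 to 60.5) in cluster 5 and 28.8 CPM (23.4 to 35.00) in monocyte-like cells, against 0.276 CPM (0.0334 to 0.996) in granulocyte-monocyte progenitor-like cells. Il6st, the gp130 chain that pairs with LIFR, was highest in cluster 1 at 155 CPM, and 9 of 17 measured LIFR and IL6-family genes were at least 2-fold higher there. Cluster 1 held 11.96% of cells and had a median of 2874 UMIs and 6.38% mitochondrial UMIs. Osm, which encodes the gp130 cytokine oncostatin M, was highest in mast or basophil-like cells at 129.8 CPM (96.4 to 171). Lif itself gave 11 UMIs in the whole library. Osmr gave 0 UMIs, with an interval that reached up to 0.0334 CPM.

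The MLL-AF9 programme genes differed between classes of the leukaemia library. In plasma cell-like cells, which need not be leukaemia cells, 23 of 24 were at least 2-fold lower, as were 24 of 24 proliferation and 15 of 20 interferon genes. Random lists matched on expression fell there too, and the interferon median lay at their percentile 9.39 against 0.0 for the programme and proliferation medians. The programme genes included the stem cell regulators Hoxa9 at 7.40 CPM against 183 CPM and Meis1 at 23.01 CPM against 627 CPM. Monocyte-like cells had 9 of 24 at least 2-fold lower, and there Id2, a differentiation-linked inhibitor of bHLH factors, was 5.81-fold (5.29 to 6.37) higher. Cluster 11 carried Pbx3, a HOX cofactor, at 1585 CPM (1550.1 to 1621) against 24.6 CPM, and Mecom (EVI1), a stem cell transcription factor, at 55.9 CPM (49.4 to 62.96) against 1673 CPM. The Pbx3 ratio was 64.5-fold (61.7 to 67.5) and fell to 36.3 at clustering resolution 2 and to 39.5 with at most 5% mitochondrial UMIs, while the Mecom ratio of 0.0334 (0.0295 to 0.0376) rose to 0.0818 without doublet removal. In cluster 12, 9 of 24 programme genes were at least 2-fold higher, with Sox4 4.39-fold (3.96 to 4.85) higher. The integrin chain Itga4, of the niche factor receptor list, was 6.99-fold (6.67 to 7.33) higher there. On the log2 scale Itga4 went from 2.80 to 0.56 with 30 neighbours, in the new cluster that overlapped cluster 12 most. In cluster 6, 19 of 24 proliferation genes were at least 2-fold higher, among them the mitotic kinase Plk1 at 17.3-fold.

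**Figure D2:**
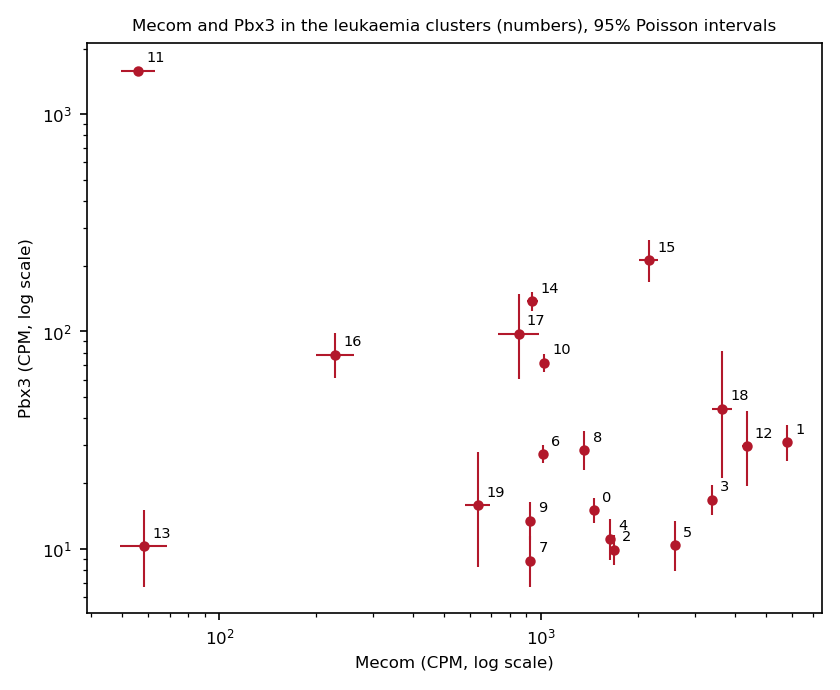
Mecom (x axis) against Pbx3 (y axis), both in CPM on log scales, for each cluster of the leukaemia library, with 95% Poisson intervals as bars and cluster numbers beside the points. Cluster 11 stands apart with high Pbx3 and low Mecom, and the plasma cell-like cells are cluster 13.

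The class shares of the stroma library address which niche cells the CD45-, Lin-, Ter119-, CD71- sort held. Fibroblast-like cells made up 33.6% (32.5 to 34.6), LepR+ mesenchymal stromal-like cells 12.7% (12.02 to 13.5) and osteolineage-like cells 10.3% (9.62 to 10.97). Chondrocyte-like cells made up 6.33% (5.80 to 6.89), endothelial-like cells 4.86% (4.40 to 5.36), skeletal muscle-like cells 4.52% (4.08 to 5.00) and pericyte or smooth muscle-like cells 0.594% (0.437 to 0.789). Haematopoietic classes, which the sort was set to exclude, together made up 4.12% (3.69 to 4.58). They were erythroid-like (1.59%), granulocyte-monocyte progenitor-like (1.55%), B cell-like (0.417%), megakaryocyte-like (0.291%) and neutrophil-like cells (0.265%). Unnamed clusters were led by Gpha2, Cilp2 and Mfap4 (cluster 4, 7.71%), by Tnn and Postn (cluster 7, 4.86%), by the joint lubricant gene Prg4 (cluster 8, 4.57%) and by the tendon genes Thbs4 and Tnmd (cluster 14, 1.73%). Cluster 11, led by Eln, Cilp and Stmn2, held 4.11% and missed the fibroblast name by a score of 0.960.

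The gene lists in the stroma library address which niche cells carried LIFR, niche factors and immune genes. Lifr was highest in LepR+ mesenchymal stromal-like cells at 1766 CPM (1742 to 1789.7) and in osteolineage-like cells at 1663 CPM (1645 to 1681). Within these classes it peaked in osteolineage cluster 12, led by Spp1 and Mmp13, at 4333 CPM (4278 to 4387), in LepR+ cluster 13 at 3226 CPM (3157 to 3297) and in LepR+ cluster 3 at 1384 CPM (1361 to 1408). Cluster 12, with a marker score of 1.149 against a minimum of 1, gave 24371 of the 33145 osteolineage Lifr UMIs, and osteolineage clusters 6 and 17 had 642 CPM (629 to 656) and 325 CPM (295 to 357). Fibroblast-like cells had 73.7 CPM (70.9 to 76.6) and skeletal muscle-like cells 30.4 CPM (24.98 to 36.7) of Lifr. Il6st was instead highest in endothelial-like cells at 800.3 CPM (771 to 830.1), and Osmr reached 262 CPM (254 to 269.8) in chondrocyte-like cells, with Il11, a gp130 cytokine, 16.8-fold (14.8 to 19.04) higher there. Clcf1, which encodes a cytokine that signals through LIFR, was 33.6-fold (29.5 to 38.2) higher in skeletal muscle-like cells. Osm reached 30.5 CPM (25.4 to 36.3) in granulocyte-monocyte progenitor-like cells and gave 0 UMIs in LepR+ mesenchymal stromal-like cells, and Lif was at most 5.59 CPM, in chondrocyte-like cells.

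**Figure D3:**
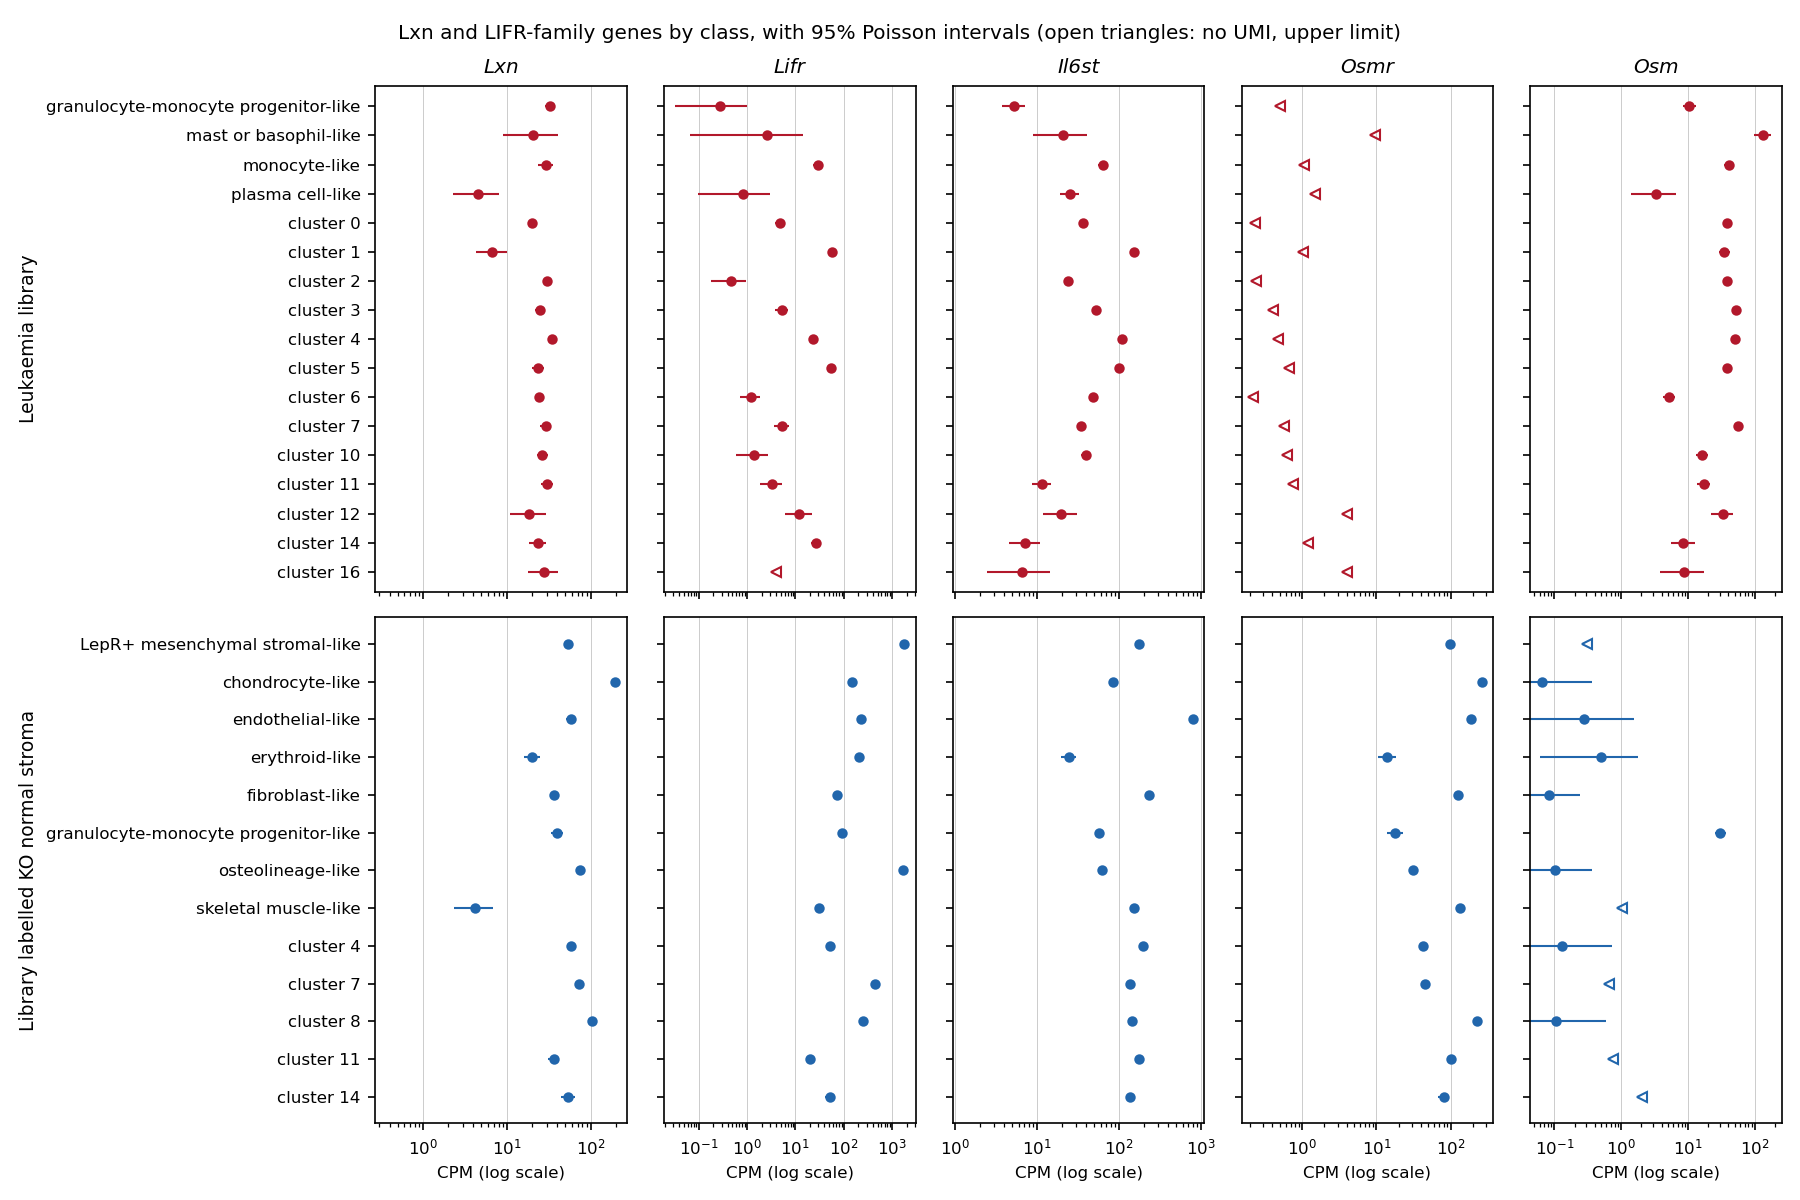
Level in CPM (x axes, log scale) of Lxn, Lifr, Il6st, Osmr and Osm in each class or cluster of at least 50 cells of the leukaemia library (top) and of the library labelled KO normal stroma (bottom). Points are summed levels with 95% Poisson intervals, open triangles mark the upper limit where no UMI was seen, and Lifr is highest in LepR+ mesenchymal stromal-like and osteolineage-like cells.

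LepR+ mesenchymal stromal-like cells had 14 of 30 niche factor genes at least 2-fold above the other stroma cells and 9 at least 2-fold below them. Cxcl12, the chemokine that retains stem cells in marrow, was 67.6-fold (66.8 to 68.5) higher at 16137 CPM, and Kitl, which encodes stem cell factor, 26.2-fold (25.6 to 26.8) higher at 2465 CPM. The same class had 12 of 13 MHC class I genes at least 2-fold higher, led by H2-Q7 at 11.1-fold (10.6 to 11.5) and H2-K1 at 8.65-fold (8.52 to 8.77), and 13 of 20 interferon genes, with Bst2, an antiviral tether, 7.57-fold (7.37 to 7.78) higher. Endothelial-like cells had 16 of 20 interferon genes at least 2-fold higher, with the antiviral gene Rsad2 18.98-fold (16.4 to 21.97) higher, and 10 of 30 niche factors higher and 12 lower by at least 2-fold. The higher ones included the selectins Sele and Selp at 547-fold and 383-fold and the Notch ligand Dll4 at 259-fold. Osteolineage-like cells held 67555 CPM of Col1a1, the main bone collagen, 25.2-fold above the rest, and most lists were lower there, with 24 of 24 proliferation, 21 of 21 inflammatory, 18 of 18 immediate-early, 22 of 30 niche factor, 12 of 20 extracellular matrix and 17 of 24 LIFR and IL6-family genes at least 2-fold lower. Lower medians were not particular to these lists, since the MHC class I median of -0.61 lay at percentile 32.07 of random lists matched on expression. The proliferation, inflammatory and niche factor medians lay at percentile 0.0. All 10 MHC class II genes were at least 2-fold higher in granulocyte-monocyte progenitor-like cells, whose cluster also held neutrophil and immunoglobulin RNA (Camp, Igkc). Of the 18 immediate-early genes, which tissue dissociation can induce, 7 were at least 2-fold higher and 3 lower in chondrocyte-like cells, with Btg2 4.87-fold higher, and 7 were higher and 0 lower in endothelial-like and in skeletal muscle-like cells.

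**Figure D4:**
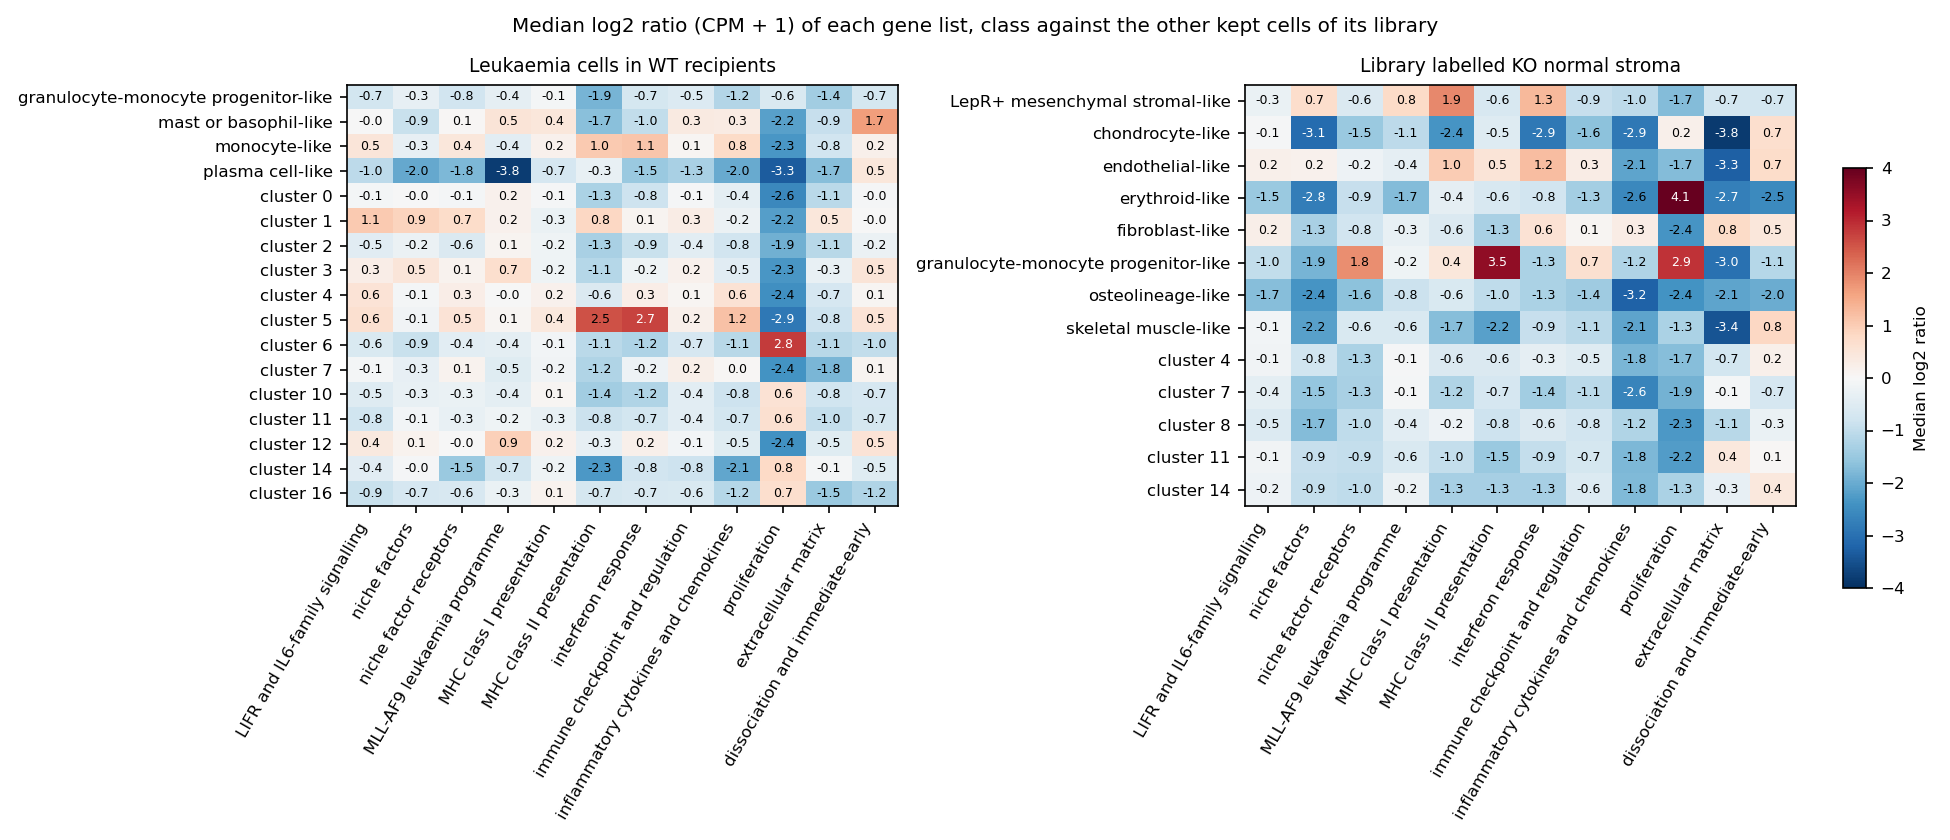
Median log2 ratio of each gene list (columns) between a class or cluster of at least 50 cells (rows of the map) and the other kept cells of the same library, with 1 CPM added, for the leukaemia library (left) and the library labelled KO normal stroma (right). Red marks higher and blue lower medians, and interferon and MHC class II genes are highest, within the leukaemia library, in cluster 5.

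The last comparison addresses how niche and leukaemia cells divide ligands and receptors. It set the library labelled KO normal stroma against leukaemia cells in WT recipients, which differed in compartment, disease and labelled host genotype together, so it answers no WT against KO question. Lifr was 52.5-fold (49.4 to 55.8) higher in stroma at 515 CPM against 9.81 CPM, a ratio that was 27.5 when per-cell CPM were averaged and 29.9 when each cell was thinned to 2000 UMIs. Il6st was 3.64-fold (3.53 to 3.75) and Lif 26.4-fold (14.5 to 53.3) higher in stroma, where Lif gave 343 UMIs. Osmr gave 15218 UMIs in stroma and 0 in the leukaemia library. It was 4289-fold higher in stroma against an assumed 3 leukaemia counts, and the lower limit of its interval was 3487-fold. Osm ran the other way and was 21.7-fold (18.7 to 25.3) higher in leukaemia cells, and its stroma-to-leukaemia ratio of 0.0461 became 0.0830 when thinned and 0.00245 without the stromal haematopoietic classes. Socs3, a feedback inhibitor induced by STAT3, was 634-fold (497 to 821) higher in stroma, and in all 15 of 24 LIFR and IL6-family genes were at least 2-fold higher in stroma and 4 in leukaemia cells, which included Il6ra and Pim1.

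Niche factors lay in the stroma, with 23 of 30 at least 2-fold higher, led by Cxcl12 at 1717 CPM against 0.217 CPM and Kitl at 315 CPM against 0.109 CPM. Angpt1, which encodes a TIE2 ligand, was 2.25-fold (2.20 to 2.29) and Tgfb1 2.36-fold (2.31 to 2.41) higher in leukaemia cells. Of 25 niche factor receptors, 12 were at least 2-fold higher in leukaemia cells and 6 in stroma. Itga4, a chain of the VCAM1 receptor VLA-4, was 31.3-fold (29.6 to 33.1) and Selplg, the P-selectin ligand, 30.4-fold (28.5 to 32.5) higher in leukaemia cells, while Il1r1 was 15.8-fold (14.7 to 16.9) and Tgfbr2 14.6-fold (13.8 to 15.5) higher in stroma. All 20 matrix genes were higher in stroma, as were 14 of 18 immediate-early genes, with the heat shock gene Hspa1a at 309.6 CPM against 1.35 CPM. Outside the lists the stroma genes with the largest log2 ratios, with 1 CPM added, were Bglap, Dcn, Prg4, Col2a1 and Bglap2, at 8889 CPM, 6098 CPM, 7636 CPM, 4093 CPM and 4005 CPM, each with under 1 CPM in leukaemia cells. By the same order they were Wfdc17, Tctex1d1, Gpr183, Ms4a6c and Tifab on the leukaemia side, with folds without the added CPM of 357-fold, 638-fold, 288-fold, 119-fold and 163-fold.

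Leukaemia cells had 13 of 24 MLL-AF9 programme genes, 10 of 10 MHC class II genes, 6 of 13 MHC class I genes and 22 of 24 proliferation genes at least 2-fold higher, and stroma had 3, 0, 2 and 0 of them at least 2-fold higher, among them Id2 at 8.83-fold (8.53 to 9.15) and H2-Q7 at 3.84-fold (3.66 to 4.04). Between the granulocyte-monocyte progenitor-like cells of both libraries the counts ran the other way for these lists other than the programme, with 15 of 24 proliferation, 6 of 8 measured MHC class II and 2 of 13 MHC class I genes at least 2-fold higher in the stroma library and 0 in the leukaemia library. All 17 measured matrix genes and 16 of 18 immediate-early genes were higher there too, and neutrophil genes and Igkc were among that cluster's leading genes, so these are not matched cells. The myeloid regulators Spi1 and Myb were 39.3-fold (37.1 to 41.6) and 29.98-fold (28.5 to 31.6) higher in leukaemia cells, and Cd74, the invariant chain, 11.6-fold (11.03 to 12.2) higher. Plasma cell-like cells, at 2830.5 CPM, held 6888 of the 17082 Cd74 UMIs of the leukaemia library, and the other cells of that library had 94.4 CPM against 13.3 CPM in stroma. The haematopoietic classes supplied most stromal UMIs of such genes, since without them the log2 ratio of stroma to leukaemia went from -5.16 to -7.98 for Spi1, from -4.79 to -8.13 for Myb and from -3.44 to -5.72 for Cd74. The immunoproteasome gene Psmb8 was 5.24-fold (5.12 to 5.36) higher in leukaemia cells, while H2-K1 was nearly level at 534 CPM and 542 CPM, with a log2 ratio of stroma to leukaemia of 0.02 that became -0.19 when haemoglobin, mitochondrial and ribosomal genes were left out of the totals. Among checkpoint genes 9 of 22 were at least 2-fold higher in leukaemia cells, including the phagocytosis inhibitor Cd47 at 3.60-fold (3.57 to 3.65), and 4 in stroma, including Cd200 at 77.8-fold (67.7 to 89.8). Stroma had 11 of 20 interferon genes at least 2-fold higher, a count of 7 with a pseudocount of 10 CPM, with Irf1 at 4.37-fold (4.23 to 4.51). Inflammatory genes split, with 16 of 21 higher in stroma, such as Ccl2 at 289-fold (201 to 432), and 5 in leukaemia cells. Cxcl1 gave 0 UMIs in leukaemia cells. It was 7311-fold higher in stroma against an assumed 3 counts, and the lower limit of its interval was 5945-fold. Ccl3 was 45.6-fold (42.7 to 48.8) higher in leukaemia cells, and 854 of the 895 stromal Ccl3 UMIs lay in granulocyte-monocyte progenitor-like cells.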

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

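All alternatives were planned before the data were examined except leaving out leukaemia cluster 1 and leaving out the stromal haematopoietic classes. Over 193 results and 2749 alternative values, 1087 values were scored as the same, 1659 as moved and 3 as reversed. Vcam1 in monocyte-like leukaemia cells went to a log2 ratio of -1.25 with 20 principal components, Il7r in mast or basophil-like cells to -0.57 when thinned, and H2-K1 between libraries to -0.19 with the cleaned total (without haemoglobin, mitochondrial and ribosomal genes). Most values scored as moved were log2 ratios, of which 1562 of 2128 were scored so. These have 1 CPM added, while the intervals of the ratios do not, so a main value can lie outside its own interval. Cxcl12 between libraries had a log2 ratio of 10.46, which lies below its fold interval of 5309 to 12329. A log2 ratio scored against such an interval can count as moved without a shift. The number scored as moved is therefore not a count of shifts from processing. Among 2265 values of folds, 269 moved by over 1.5 times, spread over 111 results. The intervals given with levels, folds and shares cover counting error only, so they do not take in shifts from processing. The cause of the shifts was not tested, except that the cleaned total moves all genes together. It moved the median gene by -0.20 (log2) between the libraries, by -0.30 to 0.12 among leukaemia classes and by -0.12 to 0.30 among stroma classes. Averaged per-cell CPM moved it by -0.01 between libraries and by up to 0.23 in plasma cell-like cells.

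The share of granulocyte-monocyte progenitor-like cells in the leukaemia library was 3.28% with at least 200 genes, 3.72% with at least 1000, 3.39% at resolution 2, 3.54% with 3000 variable genes and 3.31% with 20 principal components. No cluster took that name with at most 20% mitochondrial UMIs, without doublet removal, at resolution 0.5 or with 30 neighbours, so no value exists there. The monocyte-like share was 6.31% with at least 1000 genes, 11.6% with at most 5% mitochondrial UMIs, 12.2% without doublet removal and 13.3% at resolution 0.5. The count of interferon genes higher in monocyte-like cells was 5 with averaged CPM, 5 when thinned and 5 with a pseudocount of 10 CPM. The stromal LepR+ share was 10.1% at resolution 0.5 and 11.7% at resolution 2, and the haematopoietic share 3.65% with at least 1000 genes and 3.68% with at most 5% mitochondrial UMIs. The count of interferon genes higher in stroma was 7 with a pseudocount of 10 CPM.

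Where cells were reclustered, the values of numbered clusters below are for the new cluster with the largest overlap. With at most 5% mitochondrial UMIs the Pbx3 ratio of cluster 11 was 39.5, its Mecom ratio 0.0463, the Lifr ratio of leukaemia cluster 1 9.03 and that of stroma cluster 12 11.5. With at most 20% the Mecom ratio was 0.0424 and the Lifr ratios 9.12 and 11.7. Without doublet removal Pbx3 was 55.5, Mecom 0.0818 and Lifr in cluster 12 12.2. At resolution 2 Pbx3 was 36.3, Mecom 0.0424 and Lifr 9.72 and 9.77, and at resolution 0.5 Lifr was 5.78 and 13.9. With at least 1000 genes Mecom was 0.0401. Lifr in cluster 12 was 12.4 with at least 200 genes, 12.4 with 3000 variable genes, 13.8 with 20 principal components and 11.9 with 30 neighbours. When thinned, Pbx3 was 72.6, Mecom 0.0292, the stroma-to-leukaemia ratio of Lxn 2.57 and that of Lifr 29.9. With averaged CPM, Pbx3 was 75.3, Lifr in cluster 1 4.55, and the library ratios 2.47 for Lxn and 27.5 for Lifr. With the cleaned total Pbx3 was 67.7, Lifr in cluster 1 5.75, and the library ratios 2.40 and 45.4. Without leukaemia cluster 1 the Lifr library ratio was 62.5. The stroma-to-leukaemia ratio of Osm, 0.0461 in the main analysis, was 0.0830 when thinned and 0.00245 without the stromal haematopoietic classes. Every one of these ratios kept its side of 1. No paired analysis of WT and KO libraries was run, since matrices of only 2 libraries were analysed. Each group had 1 library and no groups were tested against each other.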

Other observations

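The tests of Lxn and of leukaemia cluster 11 were chosen after those results were seen, as was the test of few UMIs in leukaemia cluster 1, while the tests of gene span there had their predictions set before their values were seen. An earlier test of few UMIs, the ratio after thinning (5.89), was set aside because a ratio of summed CPM does not depend on depth.

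The rarer cells of the leukaemia library carried their own signals. Mast or basophil-like cells held 192 CPM (151 to 241) of Csf1, the macrophage growth factor, against 2.97 CPM, and 2217 CPM (2071 to 2371) of Angpt1 against 243 CPM. In the same cells 13 of 18 immediate-early genes were at least 2-fold higher, with Egr1 at 51.98-fold (45.3 to 59.4) and Jun at 9.50-fold (8.84 to 10.2). Cluster 14, led by haemoglobin genes and the platelet genes Pf4 and Ppbp, held 335 CPM (315 to 356) of Timp3, a metalloproteinase inhibitor. Cluster 17, of 44 cells, was led by Gngt2, Adgre4 and Pparg, genes of non-classical monocytes.

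Granulocyte-monocyte progenitor-like cells occurred in both libraries, as leukaemia cluster 9 (374 cells) and stroma cluster 16 (123 cells). Between them 11 of 23 MLL-AF9 programme genes were at least 2-fold higher in the leukaemia library and 4 in the stroma library. Hoxa9 was 9.61-fold (7.74 to 12.1), Meis1 6.12-fold (5.37 to 7.00) and Mecom 15.8-fold (13.9 to 18.1) higher in the leukaemia cells, while Pbx3 was 2.92-fold (2.26 to 3.79) higher in the stromal cluster. All 17 measured matrix genes were at least 2-fold higher in the stromal cluster, where the bone collagen gene Col1a1 gave 7275 UMIs, so RNA of stromal cells was present in it. The stromal cluster also had 15 of 24 proliferation, 16 of 18 immediate-early and 6 of 8 measured MHC class II genes at least 2-fold higher, against 0 in the leukaemia cluster for each list, and neutrophil genes (Camp, Ngp, S100a8, S100a9) and Igkc were among its leading genes, so the clusters are not a matched cell type.

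Lxn UMIs in the library labelled KO normal stroma could have several sources. Reads of the overlapping gene Gfm1 would keep the Lxn to Gfm1 ratio alike across classes, but it was 63.5 times higher in chondrocyte-like than in skeletal muscle-like cells (33.9 to 119). Free RNA would level the classes, but Lxn CPM differed 47.2-fold between the same classes (28.6 to 84.5), and after thinning to 2000 UMIs 28.1% of chondrocyte-like and 1.12% of skeletal muscle-like cells had a Lxn UMI (89.6% and 3.91% unthinned, at medians of 29262 and 9205.5 UMIs, with 3 and 2 cells too shallow to thin). A transcript that keeps its 3' end in the knockout stays open, with a Lxn UMI in 45.2% of kept stroma cells, since the deleted part is not given. WT cells or a wrong label stay open too, at 71.2 CPM, since no WT stroma matrix was analysed here.

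Leukaemia cluster 11, with high Pbx3 and low Mecom, could be a separate population. Doublets with other leukaemia cells would keep at least 0.4 of their Mecom level, but the ratio was 0.0334. Mature cells as low in Hoxa9 and Meis1 as the plasma cell-like cells would not match it, since these genes were 18.6-fold (11.7 to 31.6) and 28.5-fold (21.9 to 37.8) above those cells. No other mature class was used as a reference. Mast or basophil-like cells had 6 of 24 programme genes at least 2-fold higher and 1 lower, so other mature cells are not excluded. After thinning, 7.91% of its cells had a Mecom UMI, near the 8.11% of plasma cell-like cells and below the 85.2% of all others, and 86.3% against 3.92% had a Pbx3 UMI (24.1% and 96.2% for Mecom and 96.2% and 11.5% for Pbx3 unthinned, with 340 cells too shallow, 8 of them in cluster 11). A separate leukaemia clone, another state of the same clone, or normal progenitors or other mature cells that passed the GFP+ Lin- gate cannot be told apart here. No integration site or genotype was measured.

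Lifr was high in leukaemia cluster 1, whose cells had a median of 2874 UMIs, and its interval overlapped that of cluster 5, with a median of 7516 UMIs. Few UMIs per cell stay open as a source, since Lifr in cluster 1 was 6.90-fold (5.89 to 8.05) above all other cells but only 1.87-fold (1.31 to 2.74) above 383 cells of other clusters with UMIs in its interquartile range (2127.75 to 4009.5), which gave 36 Lifr UMIs, and 2.18-fold (1.47 to 3.37) above the 348 of them outside cluster 5. More nuclear or unspliced RNA would raise genes with long gene bodies, and across 14033 genes, which are not independent replicates, gene span and the cluster 1 ratio had a Spearman's rho of 0.441, so that source may contribute. Of the 200 genes nearest to Lifr in span, 0.5% had a ratio as high, and their median log2 ratio was 0.93 against 2.65 for Lifr. Few genes of that span thus rose as much. It cannot be decided from this whether nuclear or unspliced RNA was the whole cause. The genes were matched on span alone, and cluster 1 was the class with the highest Lifr. No biological explanation was tested, as the design names no group within this library.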
